A study of Mus musculus with 10 samples.

How the data were processed

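Both the raw counts and the log2 values were taken as deposited. Per the submitters' processing notes, reads were aligned with STAR 2.7.9 to the mouse build mm39, counted per gene with featureCounts, and handled in edgeR and limma. The counts are whole numbers of reads per gene for 55359 Ensembl gene identifiers in 10 libraries, and the submitters applied no scaling to them. The log2 values are log2 CPM (counts scaled to library size) for 13225 of these genes, which the authors deposited as a second table. They equal what limma voom gives from the deposited counts with TMM factors, an offset of 0.5 on each count and 1 on the library size, with a largest difference of 5.0e-14 against a tolerance of 1e-10. Annotation release, strand setting, handling of reads with several alignments, sequencer and read length are not given in the sources used here. Reads were not used here, so alignment was not repeated.

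Columns were matched to samples by the group name and the replicate number in the column name, and NE in the column names was read as not electroporated. No column stayed unmatched. The mark bis stands on the columns of both NoEp libraries, both mixture libraries, DRIL18 replicate 2 and IL12 replicate 2. Its meaning is not given in the sources used here. Gene symbols came from a GENCODE M21 table on GRCm38, joined by Ensembl identifier without its version. Of the identifiers, 52083 matched and 3276 did not, and 75 tested genes have no symbol. Since this build differs from the one used for counting, no coordinates were used. The symbol Aldoa stands on a pair of tested identifiers.

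Counts were analysed with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1, DESeq2 1.42.0). All 10 libraries were fitted together with 5 group means and no other term. Library sizes were scaled with TMM, which gave factors between 0.9547 and 1.0273. Genes were kept by filterByExpr with the groups, which left 15777 tested genes. Each comparison was tested with the quasi-likelihood F test with 5 residual degrees of freedom, and p-values were adjusted with the Benjamini-Hochberg method over all tested genes within the comparison. A gene counts as changed at an adjusted p under 0.05. The interaction is the log2 fold change of the mixture against Mock less the sum of the log2 fold changes of IL12 and DRIL18 against Mock. The common coefficient of variation between replicates beyond counting was 3.39%, and its median over genes 4.75%. CPM are on TMM-scaled library sizes.

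Of 41 gene lists written down before the data were examined, which hold 957 different genes, 39 had at least 3 tested members. They were tested with camera at a preset inter-gene correlation of 0.01, and p-values were adjusted over the lists of a comparison. An estimated correlation, taken from the residuals of each list, was run as an alternative. For each list, members past the test were counted with the adjustment over all genes and again with p-values adjusted over the list alone. The comparisons, tests, lists, rule for naming genes and the other alternatives were fixed before the data were examined. The alternative with the mark bis as a covariate, the choice of which lists to describe, the genes Ifngr1, Ifngr2 and Tyrobp, and the tests of explanations in the closing section were chosen after seeing the data.

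For each comparison, the genes with the 6 largest and 6 smallest log2 fold changes were named among those that passed the test, had both libraries of a group above both of the other, and reached a mean of 5 CPM in the higher group. Of each described list, up to 4 members with the largest log2 fold changes past the test were named, at any CPM. A further 12 genes fixed in advance were named whether or not they passed. Some genes that this rule selects are not reported here. For the interaction the condition on separate libraries was not applied. Between groups, where a group has 0 counts, the fold is given as a bound with 3 counts set in place of the 0. Where it has between 1 and 3 counts, a ratio is given with its 95% interval from counting alone. Fitted log2 fold changes of such genes depend on the prior count of the fit.

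The procedure was tried on simulated counts with the means of the Mock libraries, the real library sizes and the fitted spread, in which 200 genes were changed by known folds, 50 genes each, and the 21 glycolysis genes were raised 1.3-fold. In the mixture against Mock it found 50% of the genes changed 1.2-fold, 82% at 1.5-fold, 88% at 2-fold and 100% at 4-fold, with 19 of the 21 glycolysis genes, and 5 of all its 184 calls were false. For the interaction it found 28%, 78%, 82% and 100%, with 17 of the 21, and 10 of 171 calls were false. Of 37 lists without changed genes, 0 were called in either. Genes were simulated independently of each other, so this does not test list calls where genes of a list are correlated. The 200 genes were drawn from outside the lists and above a minimum CPM in Mock, so their recovery does not cover low-count genes. Far fewer genes were changed than the 10081 called between the mixture and Mock, so scaling under such broad changes was not tested. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.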

Results

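The series holds bulk RNA sequencing of pmel-1 mouse T cells, CD8 T cells whose transgenic receptor recognises the melanoma antigen gp100. Spleen cells were activated for 48 h with gp100 peptide, kept for 48 h with IL-2, electroporated with mRNA and collected for RNA 24 h later. There are 5 groups of 2 libraries each: cells without electroporation (NoEp), electroporated controls (Mock), cells given mRNA for decoy-resistant IL-18 (DRIL18), for single-chain IL-12 (IL12), or a mixture of both (mixture). Which mRNA the Mock cells received is not given in the sources used here. The libraries hold between 31281944 and 35062545 counts, with 20326 to 21358 genes detected in each. The labels call the libraries biological replicates but do not say that they came from separate animals, so all p-values measure only the spread between these samples. Libraries of the same group lay together on the first principal component. That component, with 58.9% of the variance, ran from NoEp and Mock through DRIL18 and IL12 to the mixture.

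To see whether the delivered mRNAs can be read in the libraries, counts of the cytokine genes themselves were compared. Reads assigned to Il18 (ENSMUSG00000039217) were at 1.84 ± 0.00334 CPM in Mock (mean ± SD, n = 2) and at 406 ± 7.86 CPM with DRIL18, a 220-fold difference (log2 fold change 7.78 ± 0.08 SE, adjusted p = 2.16e-34). The mixture was at 382 ± 29.7 CPM, which did not differ from DRIL18 (-0.09 ± 0.04, adjusted p = 0.0696), although Il18 passed slightly lower without mixture replicate 1 (-0.17, adjusted p = 0.00386) and with limma-voom (-0.09, adjusted p = 0.0383). NoEp (2.02 CPM) and IL12 (1.78 CPM) stayed at the Mock level. Reads of delivered mRNA and of the cells' own gene are not told apart in these counts. For IL-12 the counts show no delivery: Il12a had 3 counts over both IL12 libraries and 10 over both mixture libraries, against 7 in Mock, and Il12b had 0 in all of these. An mRNA with a changed coding sequence need not align to the mouse gene, so these low counts do not contradict the labels.

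The number of changed genes rose from DRIL18 to IL12 to the mixture. Against Mock, DRIL18 changed 3832 of 15777 tested genes (1917 higher, 1915 lower), IL12 7356 (3635 higher, 3721 lower) and the mixture 10081 (5054 higher, 5027 lower). Changes of at least 2-fold numbered 302, 1409 and 3123. Between Mock and NoEp, which differ by electroporation and by whatever mRNA the Mock cells received, 1102 genes changed, of which 18 by at least 2-fold. Ifng (ENSMUSG00000055170), the main cytokine induced by IL-12 and IL-18 in T cells, followed the same order. It stood at 1.17 ± 0.369 CPM in Mock, 17.3 ± 0.172 with DRIL18, 199 ± 15 with IL12 and 8995 ± 160 in the mixture (n = 2 each), where it made up 0.868% and 0.892% of all counts.

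**Figure D1:**
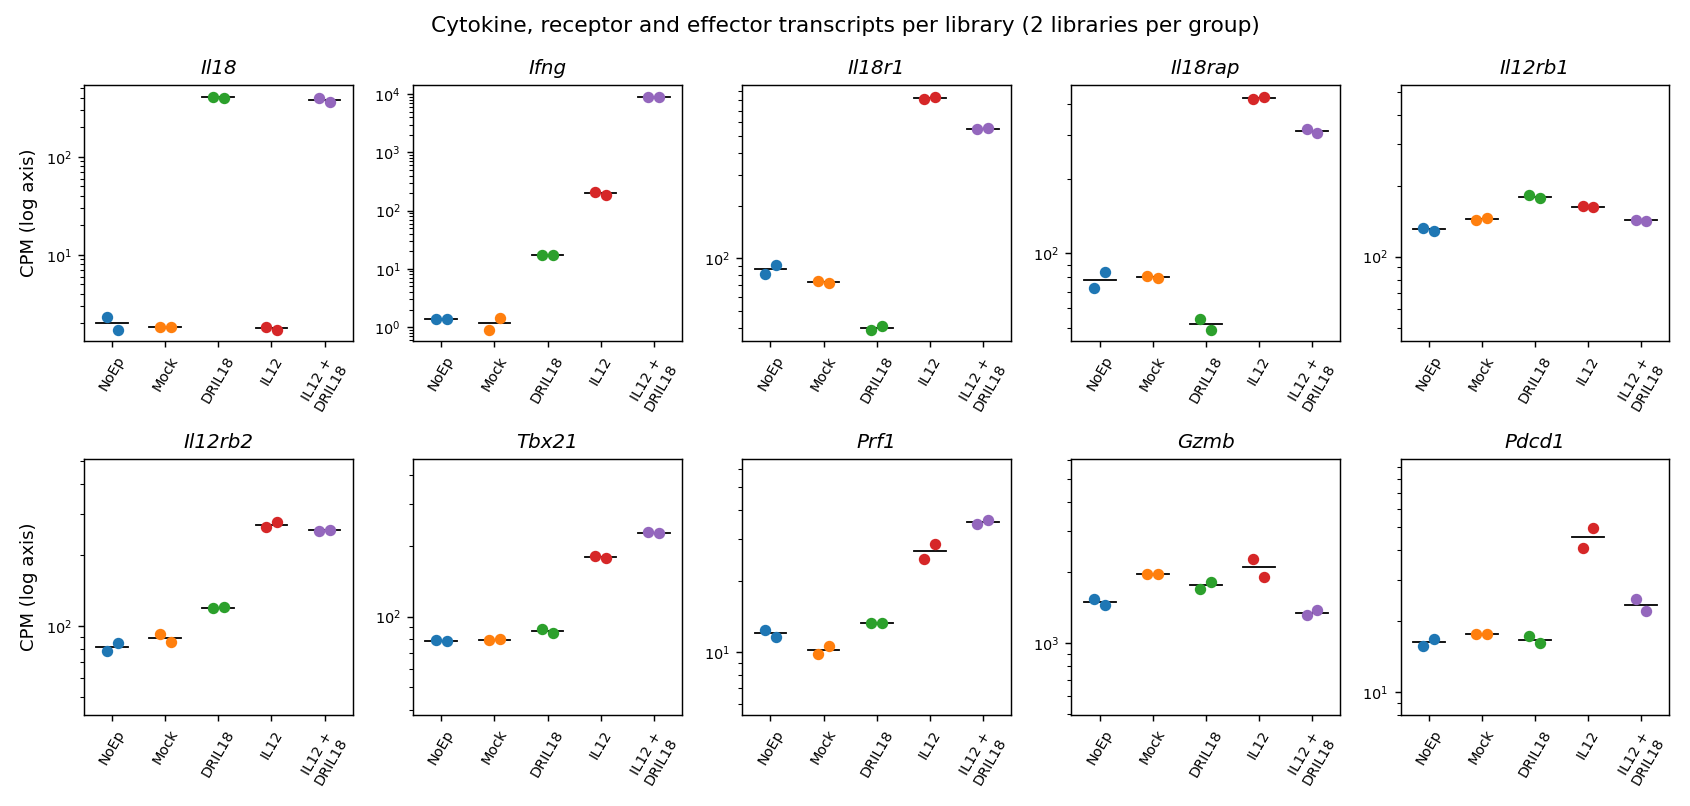
Expression of 10 genes fixed in advance, in CPM on a log axis, for the 5 groups; each point is 1 of 2 libraries and the line marks the group mean.

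To see how the electroporated controls differ from cells without electroporation, Mock was compared with NoEp. The changes were small, with a median absolute log2 fold change of 0.201 among the changed genes. The lamin gene Lmna (0.83 ± 0.15 SE, adjusted p = 0.000507; 4.04 to 7.17 CPM), the phosphatase gene Ptpn3 (0.64, adjusted p = 0.000363) and the desaturase gene Fads2 (0.61 ± 0.09, adjusted p = 9.74e-05) rose. The chemokine gene Ccl5 (-0.61 ± 0.10, adjusted p = 0.00017; 28.2 to 18.5 CPM) and the immunoglobulin gene Igkc (-0.64, adjusted p = 0.000645) fell. Among the genes fixed in advance, Gzmb (ENSMUSG00000015437) rose by 0.40 ± 0.05 (adjusted p = 1.2e-05), while Ifng, Il18rap, Prf1, Tbx21 and Pdcd1 did not pass the test. Il12rb2 (0.13, adjusted p = 0.0762) passed only under some alternatives, such as without IL12 replicate 1 (0.14, adjusted p = 0.0455). Il18r1 fell (-0.24, adjusted p = 0.00122), but did not pass without NoEp replicate 2 (-0.155, adjusted p = 0.116). Il12rb1 rose by 0.15 (adjusted p = 0.0175). Its call is lost with a fold change about as large without Mock replicate 1 (0.16, adjusted p = 0.102), Mock replicate 2 (0.14, adjusted p = 0.158) or NoEp replicate 2 (0.13, adjusted p = 0.175).

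The remaining genes with the largest changes lose their calls when 1 library is left out. Prag1 (0.81), S100a1 (0.61) and Lrp11 (0.59) were higher, and Ypel2 (-0.67), Wscd2 (-0.63), Dbp (-0.62) and Lcn4 (-0.61) lower. The fold changes stay about as large for Dbp without Mock replicate 2 (-0.605, adjusted p = 0.0756) and, without Mock replicate 1, for S100a1 (0.55, adjusted p = 0.215), Ypel2 (-0.61, adjusted p = 0.166) and Lcn4 (-0.54, adjusted p = 0.0934). They shrink for Prag1 without Mock replicate 2 (0.54, adjusted p = 0.0857) and, without NoEp replicate 2, for Lrp11 (0.44, adjusted p = 0.215) and Wscd2 (-0.415, adjusted p = 0.503).

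Genes of naive and memory cells fell in Mock: 17 of 30 were lower and 0 higher (19 adjusted over the list alone), with the IL-7 receptor gene Il7r at -0.37 ± 0.04 (adjusted p = 2.49e-07), S1pr1 at -0.34 and Klf2 at -0.30. Migration and adhesion genes also fell, 10 of 27 lower and 0 higher (12 adjusted over the list alone), including Ccr2 (-0.53) and Itgae (-0.46, adjusted p = 6.53e-08). Lists of other cell types were lower beside them. Genes of gamma-delta T cells had 4 of 8 lower and 0 higher (4 adjusted over the list alone; adjusted p = 0.121 with an estimated correlation) and a median of -0.25. Genes of CD4 and regulatory T cells had 2 of 12 lower and 1 higher (4 and 1 adjusted over the list alone, adjusted p = 0.176 with an estimated correlation and 0.193 without NoEp replicate 1), and dendritic cell genes 1 of 14 lower and 0 higher (3 adjusted over the list alone, adjusted p = 0.33 with an estimated correlation, 0.283 without NoEp replicate 1 and 0.0615 with fry). Cell cycle genes rose slightly, 22 of 49 with 0 lower (30 adjusted over the list alone) and a median of 0.12. Their largest members, Gins2 and Ccne2 at 0.22, lose the call without Mock replicate 1 while the fold changes stay about as large (0.23, adjusted p = 0.185, and 0.21, adjusted p = 0.124).

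Metabolic and stress genes of Mock cells rose by small steps. Glycolysis genes were higher for 11 of 21 with 0 lower (14 adjusted over the list alone), among them Tpi1 (0.32) and Pgam1 (0.30); for the list, adjusted p = 0.292 with an estimated correlation and 0.132 with the rotation test fry. Integrated stress and amino acid genes had 7 of 30 higher and 0 lower (9 adjusted over the list alone; adjusted p = 0.0681 with an estimated correlation), such as Asns (0.47) and Psat1 (0.25). Cholesterol synthesis had 8 of 26 higher and 0 lower (10 adjusted over the list alone; adjusted p = 0.0539 with an estimated correlation), with Sqle at 0.26. Heat shock genes had 7 of 17 higher and 0 lower (8 adjusted over the list alone; adjusted p = 0.275 with an estimated correlation and 0.0615 with fry), with Hsp90aa1 at 0.26 and Hspd1 at 0.23. Of 20 B cell genes 3 were lower and 0 higher (3 adjusted over the list alone; adjusted p = 0.176 with an estimated correlation), among them Igkc and Cd74 (-0.38). The number of changed genes depends on the samples: 172 genes pass, 156 of them among the 1102, when the mark bis, which separates all Mock from all NoEp libraries, is a covariate, and 242 pass without Mock replicate 1. With that covariate the fold changes of Lmna (0.82 ± 0.22 SE, adjusted p = 0.0639), Igkc (-0.61 ± 0.17, adjusted p = 0.0816) and Sqle (0.23 ± 0.06, adjusted p = 0.0759) stay about as large, but their calls are lost with the wider standard errors. Those of Il18r1 (-0.19 ± 0.06, adjusted p = 0.162) and Hspd1 (0.18 ± 0.06, adjusted p = 0.149) are smaller and also lost.

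To test what decoy-resistant IL-18 did alone, DRIL18 was compared with Mock. Ifng rose 14.9-fold (3.90 ± 0.12 SE, adjusted p = 1.47e-21), and the IFN-γ target genes Serpina3f (4.52 ± 0.14, adjusted p = 3.27e-21; 1.29 to 29.7 CPM) and Cxcl10 (3.64 ± 0.24, adjusted p = 3.95e-13; 0.509 to 6.39 CPM) rose with it. Upp1 (4.25) and Sema6d (3.53) also rose. The transcription factor gene Eomes (-1.42; 13.5 to 5.04 CPM) fell, with Aqp9 (-1.48), Prag1 (-1.48), Mycn (-1.46), Drc1 (-1.43) and Sgk1 (-1.41). Both IL-18 receptor genes fell: Il18r1 (ENSMUSG00000026070) by 0.87 ± 0.05 (adjusted p = 2.25e-14) and Il18rap (ENSMUSG00000026068) by 0.63 (adjusted p = 1.56e-10). The IL-12 receptor genes Il12rb2 (0.42, adjusted p = 1.22e-08) and Il12rb1 (0.31, adjusted p = 1.44e-07) rose. Small changes of Prf1 (0.37), Gzmb (-0.16) and Tbx21 (0.12) lose the call when 1 library is left out. Prf1 has 0.32 (adjusted p = 0.0678) without Mock replicate 1, and without DRIL18 replicate 1 Gzmb has -0.11 (adjusted p = 0.268) and Tbx21 0.095 (adjusted p = 0.249). DESeq2 gives Gzmb -0.17 (adjusted p = 0.233) and Tbx21 0.12 (adjusted p = 0.0567), without calling them. Pdcd1 did not change (adjusted p = 0.599).

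IFN-γ response and antigen presentation genes rose broadly with DRIL18: 35 of 41 were higher and 0 lower (36 adjusted over the list alone), with a median of 0.62 and Serpina3g (2.99) and Ciita (1.85) among the largest. NF-κB targets, which lie downstream of the IL-18 receptor, had 19 of 35 higher and 2 lower (19 and 2 adjusted over the list alone), among them Cd83 (1.46), Relb (1.43), Nfkbia (1.37) and Tnfrsf9 (1.07). Interferon-stimulated genes had 21 of 43 higher and 1 lower (23 and 1 adjusted over the list alone; adjusted p = 0.071 with an estimated correlation). Among them, Isg15 rose by 0.68, but did not pass without Mock replicate 2 (0.59, adjusted p = 0.0622). Cytokine and chemokine genes of effector cells had 8 of 23 higher and 4 lower (9 and 4 adjusted over the list alone; adjusted p = 0.115 with an estimated correlation), led by Csf2 (2.33), Ccl3 (1.52) and Tnfsf4 (1.34).

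Glycolysis genes rose with DRIL18, 17 of 21 with 0 lower (18 adjusted over the list alone; adjusted p = 0.142 with an estimated correlation), with Tpi1 at 0.68 and Pfkl at 0.62. Migration and adhesion genes mostly fell: 17 of 27 were lower and 5 higher (18 and 5 adjusted over the list alone; adjusted p = 0.0852 with an estimated correlation), among them the integrin genes Itga1 (-1.73) and Itgax (-1.11) and the chemokine receptor gene Ccr2 (-1.18). A list of dendritic cell genes had 7 of 14 higher and 2 lower (8 and 2 adjusted over the list alone), with Cd74 (2.30), Batf3 (1.95), H2-Aa (1.47) and H2-Eb1 (1.43). Of its 20 genes, 5 stand on another list as well, among them Cd74 and Batf3, and the MHC class II genes are also targets of Ciita. B cell genes had 5 of 20 higher and 0 lower (6 adjusted over the list alone; adjusted p = 0.071 with an estimated correlation), with Ighd at 0.58. A list of NK cell genes had 4 of 10 lower and 0 higher (4 adjusted over the list alone), including Eomes, Gzma (-0.85) and Txk (-0.34). The number of changed genes falls to 2525 without Mock replicate 2.

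To test what IL-12 did alone, IL12 was compared with Mock. Ifng rose 171-fold (7.42 ± 0.08 SE, adjusted p = 2.25e-33). Both IL-18 receptor genes rose, the opposite of their fall with DRIL18: Il18r1 went from 72.8 ± 1.15 to 827 ± 19.2 CPM (n = 2; 3.51 ± 0.05, adjusted p = 4.39e-32) and Il18rap from 80.2 ± 0.91 to 424 ± 7.31 CPM (2.40 ± 0.05, adjusted p = 5.63e-27). The integrin gene Itgae, which encodes CD103, fell from 192 to 7.30 CPM (-4.72 ± 0.06, adjusted p = 7.94e-32), and the IFN-γ receptor gene Ifngr2 from 14.1 to 1.38 CPM (-3.35 ± 0.15). Among the genes fixed in advance, Il12rb2 (ENSMUSG00000018341; 1.60 ± 0.04, adjusted p = 9.26e-24), Prf1 (1.40, adjusted p = 1.92e-14), Pdcd1 (1.36, adjusted p = 1.13e-14) and Tbx21 (1.17, adjusted p = 4.65e-21) rose, and Il12rb1 rose by 0.18 (adjusted p = 0.000268). Gzmb did not pass (0.08, adjusted p = 0.182) except without IL12 replicate 2 (0.21) or without the filter on low counts (0.09, adjusted p = 0.00804). Without IL12 replicate 1 its value was -0.05, so its direction rests on a single library.

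The largest rises with IL12 were in genes with few or no Mock counts. Rufy4 and Unc5c, with 0 counts in Mock, rose at least 127-fold each. Serpinb5 (1 count in Mock) had a ratio of 382 (95% counting interval 68.2 to 15100) and Cxcr1 (2 counts) a ratio of 182 (50.1 to 1510). P2rx3 rose from 0.0871 to 94.5 CPM (10.02 ± 0.17, adjusted p = 6.41e-29). Besides Itgae and Ifngr2, the largest falls were in Rtp4 (-4.35), Cbfa2t3 (-3.51), Rxra (-3.25) and Tspan32 (-3.19).

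Lists of effector function rose with IL12. Effector transcription factors had 17 of 22 higher and 2 lower (18 and 2 adjusted over the list alone), with Hlx (5.39), Hopx (2.71) and Bhlhe40 (2.21). Genes of IL-12 and IL-18 receptor signalling had 17 of 26 higher and 7 lower (17 and 7 adjusted over the list alone), with Pim2 (3.11) and Gadd45g (3.10). Costimulatory receptors had 11 of 17 higher and 4 lower (11 and 5 adjusted over the list alone), including Slamf7 (1.90), Cd86 (1.76) and Icos (1.67). Cytotoxic granule genes had 12 of 24 higher and 5 lower (12 and 5 adjusted over the list alone), among them Gzmk (3.42), Gzmd (2.04) and Stx11 (1.44), though reads of the similar genes Gzmc and Gzmd may be hard to assign. Effector cytokines and chemokines had 10 of 23 higher and 7 lower (11 and 8 adjusted over the list alone; adjusted p = 0.132 with an estimated correlation and 0.136 without the filter on low counts), including Csf2 (4.35), Csf1 (2.87) and Il21, which had 0 Mock counts and rose at least 7.73-fold.

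Cholesterol synthesis genes rose almost throughout with IL12, 24 of 26 with 0 lower (25 adjusted over the list alone) and a median of 0.94, including Fdps (1.68), Lss (1.66), Cyp51 (1.47) and Msmo1 (1.45). Glycolysis genes had 19 of 21 higher and 0 lower (19 adjusted over the list alone; adjusted p = 0.0923 with an estimated correlation), among them Aldoc (2.19), Slc16a3 (2.14), Hk2 (2.07) and Slc2a1 (1.82). The IL12 libraries differed from each other in some of these genes. Slc16a3 stood at 219.7 ± 45.58 CPM with IL12 (mean ± SD, n = 2) against 49.92 ± 4.322 in Mock, and Aldoc at 27.78 ± 7.961 against 6.096 ± 0.2557. Interferon-stimulated genes mostly fell, although Ifng rose: 26 of 43 were lower and 7 higher (26 and 8 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation). Rtp4 and Cmpk2 (-3.12) fell, and Ifi204 rose by 3.15. The IFN-γ response list was called higher, with 17 of 41 higher and 10 lower (18 and 11 adjusted over the list alone; adjusted p = 1.01e-08, and 0.16 with an estimated correlation), led by Gbp2 (3.26) and Cxcl10 (2.82). Its median was 0.085 and its mean 0.453. Gamma-delta T cell genes had 4 of 8 lower and 1 higher (6 and 1 adjusted over the list alone, adjusted p = 0.121 with an estimated correlation), with Tcrg-C1 at -1.80. Genes of CD4 and regulatory T cells were called higher, with 4 of 12 higher and 3 lower (4 and 4 adjusted over the list alone), among them Il2ra (2.26) and Ikzf2 (-1.45). Their median was -0.18, the sign opposite to that of the test, but 0.48 without Mock replicate 1, so its direction rests on 1 library. The call is lost there, without Mock replicate 2 and without mixture replicate 1. It is also lost with an estimated correlation (adjusted p = 0.169) and without the filter on low counts (adjusted p = 0.506).

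**Figure D2:**
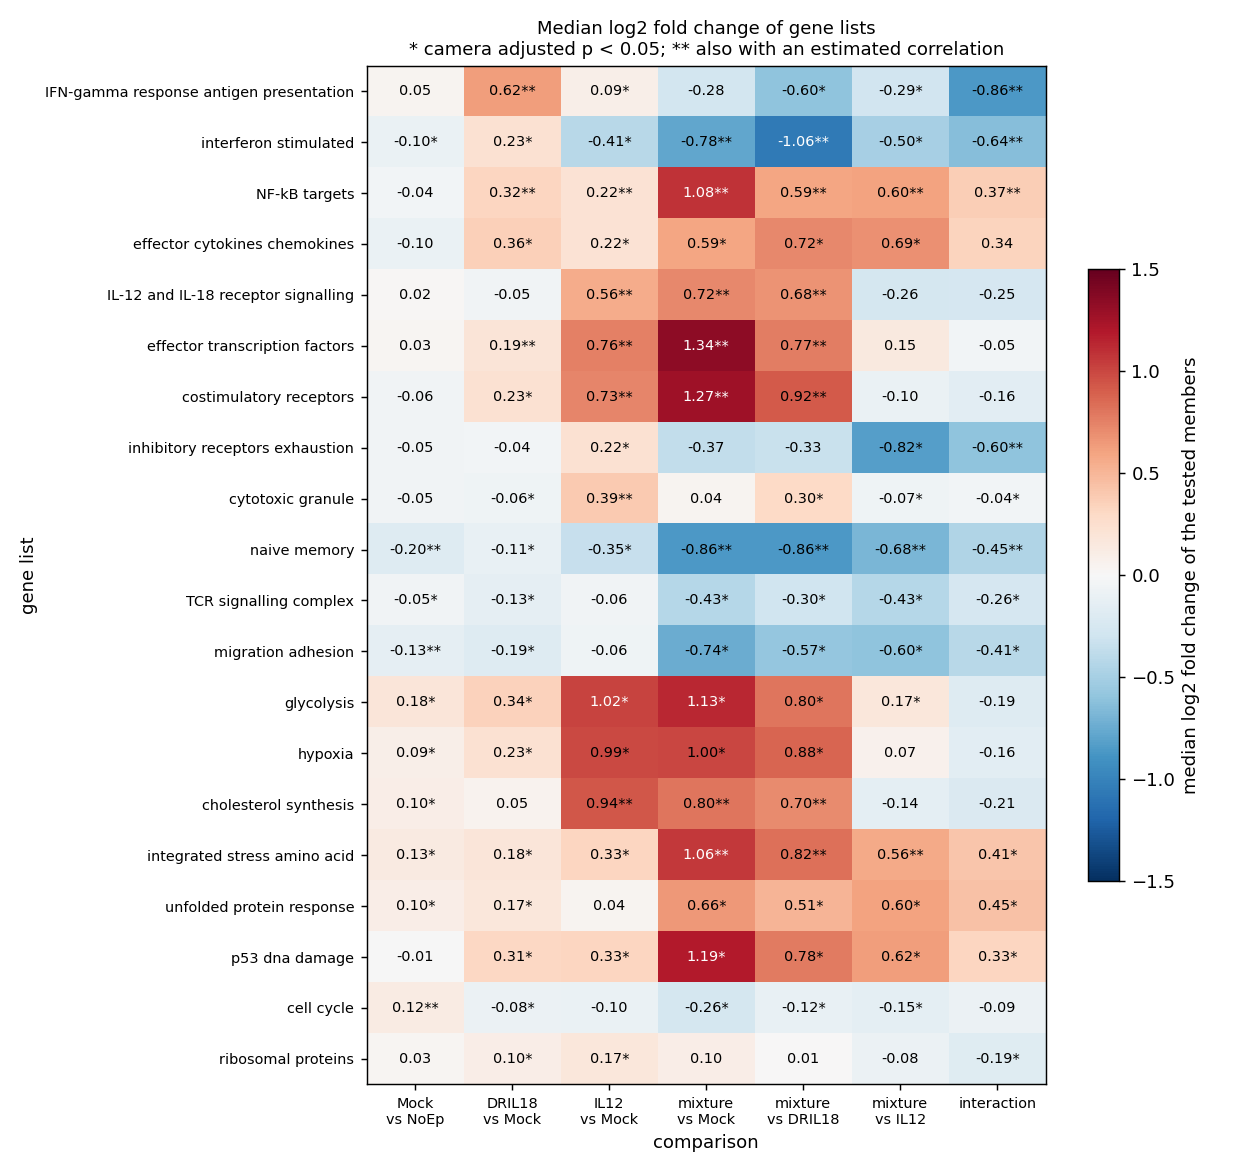
Median log2 fold change of the members of 20 gene lists in 7 comparisons; an asterisk marks lists past the camera test and a double asterisk those that also pass with an estimated correlation.

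To test the joint action of both cytokines, the mixture was compared with Mock. Ifng rose 7730-fold (12.92 ± 0.08 SE, adjusted p = 7.6e-41). Cytokine genes absent from Mock came up: Il22 reached 33.2 ± 2.8 CPM (n = 2; at least 763-fold) and had 0 counts in Mock, DRIL18 and IL12, Il6 reached 23.1 CPM (at least 530-fold) and Il13 15.4 CPM (at least 353-fold). With the mark bis as a covariate the fitted log2 fold change of Il22 is the same as without it (13.12), but the fit gives no standard error and does not call the gene (adjusted p = 1). Itgae fell 83.7-fold, from 192 to 2.29 CPM (-6.39 ± 0.07, adjusted p = 1.7e-33). Prf1 (1.81, adjusted p = 4.05e-18), Tbx21 (1.51, adjusted p = 1.93e-24), Il18r1 (2.92, adjusted p = 1.8e-30), Il18rap (1.96, adjusted p = 4.01e-25) and Il12rb2 (1.51) rose, and Pdcd1 rose by 0.41 (adjusted p = 0.00014). Gzmb fell by 0.55 (adjusted p = 6.51e-11) and Il12rb1 did not change (adjusted p = 0.712).

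Of the other large rises in the mixture, Gcnt3 went from 0 counts to 73.1 CPM (at least 1680-fold), Fam107a from 0 counts to 17.3 CPM (at least 397-fold), and Sema3b, with 2 Mock counts, had a ratio of 5850 (95% counting interval 1620 to 48300). The largest falls after Itgae were in the E-cadherin gene Cdh1 (-6.33; 7.38 to 0.0883 CPM), Cd7 (-5.37; 11.7 to 0.281 CPM), Ifi208 (-4.97), Kcna2 (-4.94) and Rgs10 (-4.64). Ifi208 belongs to a family of similar genes between which reads may be hard to assign.

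NF-κB targets rose in the mixture, 28 of 35 with 1 lower (28 and 1 adjusted over the list alone) and a median of 1.08, among them the costimulatory receptor genes Tnfrsf4 (3.97; 8.18 to 128 CPM) and Tnfrsf9 (3.16) with Cd83 (3.12). Effector cytokines and chemokines had 16 of 23 higher and 5 lower (16 and 5 adjusted over the list alone; adjusted p = 0.115 with an estimated correlation), led by Csf2 (7.02; 0.236 to 30.7 CPM) and Tnfsf4 (3.70). Type 2, type 17 and regulatory cytokine genes had 10 of 17 higher and 4 lower (10 and 4 adjusted over the list alone; adjusted p = 0.0994 with an estimated correlation). Besides Il22, Il6 and Il13 they include the IL-33 receptor gene Il1rl1 (7.13; 0.782 to 110 CPM), which IL12 alone brought to 103.5 CPM.

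Naive and memory genes fell in the mixture, 25 of 30 with 3 higher (25 and 3 adjusted over the list alone), including Klf2 (-3.63), Il6ra (-3.57), Nsg2 (-2.86) and Klf3 (-2.66). Genes of the T cell receptor complex had 24 of 28 lower and 4 higher (24 and 4 adjusted over the list alone; adjusted p = 0.0994 with an estimated correlation), such as Dgka (-1.64), Cd5 (-1.36) and Cd3g (-1.06). Interferon-stimulated genes fell as well, with 31 of 43 lower and 5 higher (31 and 5 adjusted over the list alone), including Rtp4 (-3.99), Cmpk2 (-3.78) and Rsad2 (-3.20). Genes of selectin ligands and sialylation had 18 of 37 lower and 10 higher (18 and 12 adjusted over the list alone; adjusted p = 0.0948 with an estimated correlation), with the sialyltransferase genes St3gal6 (-2.40), St8sia1 (-2.20) and St8sia4 (-1.95). Beside these falls, gamma-delta T cell genes had 5 of 8 lower and 0 higher (5 adjusted over the list alone, adjusted p = 0.115 with an estimated correlation), with Tcrg-C1 at -2.49. NK cell genes had 6 of 10 lower and 2 higher (6 and 2 adjusted over the list alone). Their call is lost with an estimated correlation (adjusted p = 0.115) and without the filter on low counts (adjusted p = 0.0967). Dendritic cell genes had 10 of 14 higher and 2 lower (10 and 2 adjusted over the list alone, adjusted p = 0.145 with an estimated correlation), with Batf3 (2.63) and Cd74 (2.46) higher. IFN-γ response genes split, 16 of 41 higher and 23 lower (16 and 23 adjusted over the list alone), and the list was not called (adjusted p = 0.819). Its median was -0.27 and its mean 0.33, and the test had the sign of the median. Cxcl10 rose by 6.07 and Serpina3f by 2.76, whereas Cxcl9 (2.48) does not pass without Mock replicate 2 (1.55, adjusted p = 0.205).

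Stress genes rose in the mixture. Integrated stress and amino acid genes had 26 of 30 higher and 0 lower (26 adjusted over the list alone), with Slc7a3 (5.57), Cth (5.51), Vldlr (4.05) and Nupr1 (4.01). Genes of the unfolded protein response had 21 of 24 higher and 0 lower (21 adjusted over the list alone; adjusted p = 0.115 with an estimated correlation), including Ern1 (2.61), Hyou1 (1.23), Manf (1.05) and Hspa5 (0.97). Glycolysis genes had 18 of 21 higher and 1 lower (18 and 1 adjusted over the list alone; adjusted p = 0.115 with an estimated correlation), with Hk2 (3.80), Slc16a3 (2.50) and Slc2a1 (2.16).

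To see what IL-12 added to DRIL18, the mixture was compared with DRIL18, which changed 9042 genes (4466 higher, 4576 lower). Ifng rose 519-fold (9.02 ± 0.06 SE, adjusted p = 1.1e-39), Il18r1 by 3.79 (adjusted p = 2.12e-32) and Il18rap by 2.58 (adjusted p = 2.13e-27). Itgae fell from 140.8 to 2.29 CPM (-5.94 ± 0.08, adjusted p = 3.41e-32). Gcnt3 (at least 1670-fold), Il22 (at least 759-fold), Prss35 (at least 215-fold), Unc5c (at least 162-fold) and Cxcr1 (at least 134-fold) rose from 0 counts, and Sema3b rose from 0.131 to 170 CPM. Cd7 (-4.53), Ifi208 (-4.43), Rtp4 (-4.27), Ifi213 (-4.08) and Cmpk2 (-4.07) fell. Of the other genes fixed in advance, Prf1 (1.43), Tbx21 (1.38), Il12rb2 (1.09) and Pdcd1 (0.49) rose, while Gzmb (-0.39) and Il12rb1 (-0.33) fell.

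Adding IL-12 lowered interferon responses that DRIL18 had raised, although Ifng was higher. Interferon-stimulated genes had 36 of 43 lower and 2 higher (36 and 2 adjusted over the list alone), with Ifit1bl1 (-3.44) and Rsad2 (-3.37). IFN-γ response genes had 30 of 41 lower and 8 higher (31 and 9 adjusted over the list alone; adjusted p = 0.0789 with an estimated correlation). Gbp10 (-3.93; 41.2 to 2.69 CPM) and Gbp6 (-2.58; 143 to 24.1 CPM) fell, members of a family with similar sequences, while Cxcl10 rose by 2.43 and Cxcl11 at least 16.8-fold from 0 counts. Gamma-delta T cell genes were lower as well, 5 of 8 with 0 higher (5 adjusted over the list alone, adjusted p = 0.134 with an estimated correlation), with Tcrg-C1 at -2.01. Cholesterol synthesis genes rose, 22 of 26 with 1 lower (23 and 1 adjusted over the list alone), among them Hsd17b7 (1.38), Msmo1 (1.29) and Lss (1.26). Receptor signalling genes of IL-12 and IL-18 had 15 of 26 higher and 9 lower (16 and 9 adjusted over the list alone), with Gadd45g (3.59) and Gadd45b (1.73). NF-κB targets had 26 of 35 higher and 2 lower (26 and 4 adjusted over the list alone), with Tnfrsf4 (3.30), Tnfrsf9 (2.09), Nfkbiz (2.08) and Cd83 (1.66).

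To see what DRIL18 added to IL-12, the mixture was compared with IL12, which changed 8232 genes (4075 higher, 4157 lower). Ifng rose 45.1-fold (5.50 ± 0.05 SE, adjusted p = 5.54e-36). Il22 (at least 691-fold), Il6 (at least 480-fold), Fam107a (at least 359-fold), Il13 (at least 320-fold) and Acox2 (at least 156-fold) rose from 0 counts, and Gcnt3, with 2 counts in IL12, had a ratio of 2280 (95% counting interval 631 to 18800). The receptor tyrosine kinase gene Ret fell from 13.1 to 0.0737 CPM (-7.40), Timp2 from 16.55 to 0.383 CPM (-5.42) and Nt5e, which encodes CD73, from 44.2 to 2.52 CPM (-4.13 ± 0.11, adjusted p = 4.98e-24). Matn2 (-4.54), Slc9a2 (-3.96) and Cass4 (-3.92) also fell. Pdcd1 (ENSMUSG00000026285) fell by 0.95 (adjusted p = 1.63e-11), Gzmb by 0.64 (adjusted p = 4.93e-12), Il18r1 by 0.59 (adjusted p = 5.95e-14), Il18rap by 0.45 (adjusted p = 5.56e-10) and Il12rb1 by 0.20 (adjusted p = 6.54e-05). Prf1 (0.41, adjusted p = 2.86e-05) and Tbx21 (0.34, adjusted p = 5.64e-09) rose. Il12rb2 did not pass (-0.09, adjusted p = 0.0754) except without IL12 replicate 1 (-0.12, adjusted p = 0.0343).

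NF-κB targets rose over IL12, 25 of 35 with 4 lower (26 and 4 adjusted over the list alone), including Cd83 (2.90), Tnfrsf4 (2.63), Nfkbia (2.31; 45.1 to 224 CPM) and Bcl2l1 (1.87). Genes of the unfolded protein response had 21 of 24 higher and 0 lower (23 adjusted over the list alone; adjusted p = 0.0966 with an estimated correlation), with Ern1 (2.44), Derl3 (1.38) and Dnajb9 (1.12). Inhibitory receptor and exhaustion genes had 13 of 22 lower and 8 higher (14 and 8 adjusted over the list alone; adjusted p = 0.0574 with an estimated correlation). Lag3 (-2.37; 162 to 31.3 CPM) and Cd200r1 (-1.85) fell with Nt5e, whereas Nr4a1 rose by 2.67. Naive and memory genes had 21 of 30 lower and 4 higher (21 and 4 adjusted over the list alone), such as Klf2 (-2.09), Slamf6 (-1.93) and Xcl1 (-1.77). Migration and adhesion genes had 18 of 27 lower and 6 higher (18 and 6 adjusted over the list alone; adjusted p = 0.0611 with an estimated correlation), such as Itga1 (-2.50), Ccr2 (-1.91) and Itgax (-1.87). Lists of 2 other cell types were higher: B cell genes with 11 of 20 higher and 0 lower (12 adjusted over the list alone, adjusted p = 0.0973 with an estimated correlation), among them Spib (2.85) and Igkc (1.47), and dendritic cell genes with 10 of 14 higher and 3 lower (10 and 3 adjusted over the list alone, adjusted p = 0.149 with an estimated correlation), among them Cd74 (2.28) and Batf3 (1.94).

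To set the single cytokines against each other, IL12 was compared with DRIL18, which changed 6235 genes (2987 higher, 3248 lower). Ifng was 11.5-fold higher with IL12 (3.52 ± 0.05 SE, adjusted p = 5.64e-30) and Il18r1 20.8-fold higher (4.38, adjusted p = 7.16e-34), with Il18rap at 3.03 (adjusted p = 4.21e-29). P2rx3 (8.93), Il1rl1 (7.43; 0.598 to 103.5 CPM) and Coro6 (6.92) were higher with IL12, and Serpinb5 (at least 127-fold), Unc5c (at least 126-fold) and Cxcr1 (at least 121-fold) had 0 counts with DRIL18. Il18 (-7.83, adjusted p = 1.79e-34), Rtp4 (-4.63), Itgae (-4.27), Serpina3f (-4.03; 29.7 to 1.81 CPM), Rxra (-3.66) and Cmpk2 (-3.40) were lower. Pdcd1 (1.44), Il12rb2 (1.18), Tbx21 (1.05), Prf1 (1.02) and Gzmb (0.25, adjusted p = 0.00023) were higher, and Il12rb1 was lower (-0.14, adjusted p = 0.00443), but did not pass without DRIL18 replicate 1 (-0.115, adjusted p = 0.0754).

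IFN-γ response genes were lower with IL12 than with DRIL18 despite more Ifng: 28 of 41 were lower and 8 higher (28 and 8 adjusted over the list alone; adjusted p = 0.181 with an estimated correlation), with Serpina3g (-3.04), Gbp10 (-2.59) and Ciita (-1.93). Dendritic cell genes were lower with them, 9 of 14 with 1 higher (9 and 1 adjusted over the list alone, adjusted p = 0.117 with an estimated correlation), among them Cd74 (-2.12) and H2-Aa (-1.51). B cell genes had 9 of 20 lower and 0 higher (9 adjusted over the list alone, adjusted p = 0.0563 with an estimated correlation), with Ighm at -1.04 and Cd79b at -1.05. Cytotoxic granule genes had 14 of 24 higher and 3 lower (14 and 3 adjusted over the list alone), with Gzmk (2.90), Gzma (2.35), Fasl (1.97) and, lower, Gzmc (-2.58). NK cell genes, a list that also holds Gzma, had 7 of 10 higher and 0 lower (7 adjusted over the list alone) and passed with an estimated correlation (adjusted p = 0.0243). Cholesterol synthesis genes had 24 of 26 higher and 0 lower (25 adjusted over the list alone), led by Lss (1.92). Receptor signalling genes of IL-12 and IL-18 had 16 of 26 higher and 7 lower (16 and 7 adjusted over the list alone), with Gadd45g (3.33) and, lower, Irak3 (-2.99).

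To test whether both cytokines together did more than their separate effects multiplied, the interaction was tested on the log2 scale. Ifng exceeded the product 3.03-fold (1.60 ± 0.19 SE, adjusted p = 3.57e-08): the product of the separate effects is 2960 CPM, their sum 215 CPM, and the mixture held 8995 CPM. The interaction passed for 4993 of 15777 genes, 2296 above the product and 2697 below it. Against the sum of the separate effects on the CPM scale, 2349 of these genes lay above and 2644 below, and 2290 and 2638 lay on the same side of both expectations. For genes lowered by both treatments this sum can turn negative, as for Klf2 (-0.662 CPM), and such genes lie above it by construction. The glutathione transferase gene Gstm1 lay far above the product, with 0.864 CPM in Mock, 1.00 with DRIL18, 0.753 with IL12 and 207 in the mixture (7.89 ± 0.40, adjusted p = 2.54e-16). Itgb5 (6.25; 47.4 CPM in the mixture) and Kctd14 (6.23; 26.4 CPM in the mixture) were likewise far higher in the mixture than in any other group.

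**Figure D3:**
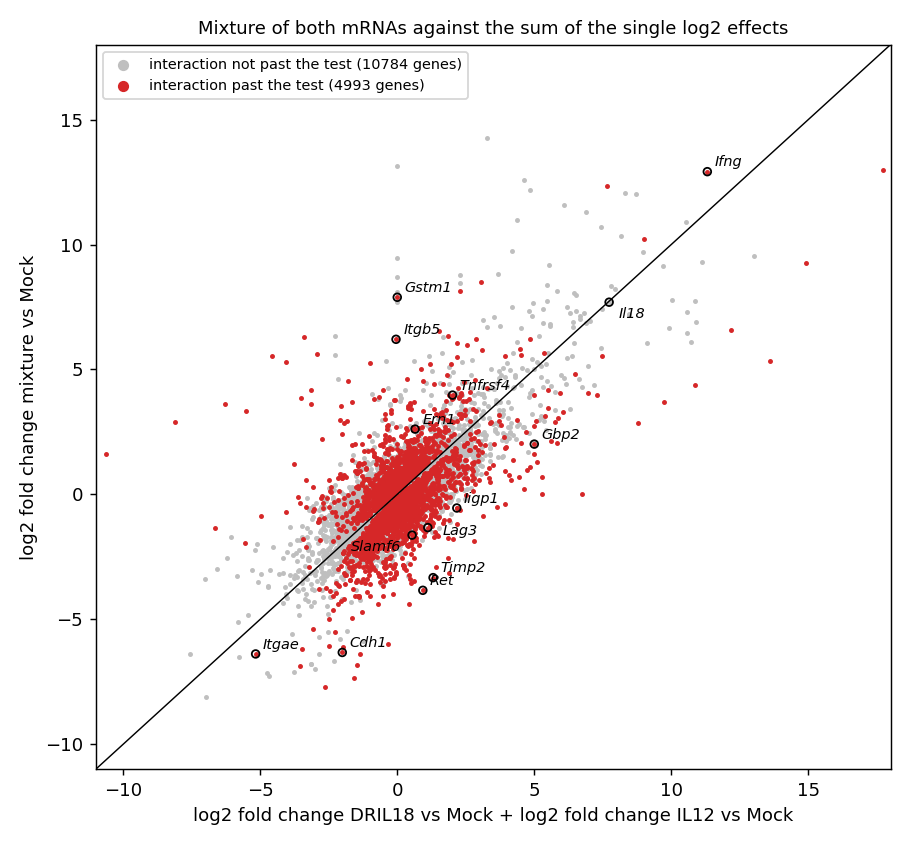
For each tested gene, the log2 fold change of the mixture against Mock (vertical) over the sum of the log2 fold changes of DRIL18 and IL12 against Mock (horizontal); red points are the 4993 genes past the interaction test, grey points the other genes, and the line marks equality.

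Genes far below the product were Ret (-4.77), Timp2 (-4.64), Cdh1 (-4.32) and Matn2 (-4.12), of which Cdh1 lay above the sum. That sum was only 0.0078 CPM, with 0.0883 CPM in the mixture, so the place of Cdh1 above it tells little. The remaining large values shrink and lose their calls when 1 library is left out. Without Mock replicate 1, Gpr83 goes from 8.53 to 3.37 (adjusted p = 0.959), Plagl1 from 5.84 to 1.49 (adjusted p = 0.889) and Timp3 from 5.42 to 1.765 (adjusted p = 0.908). Slc9a2 goes from -3.80 to -2.83 without DRIL18 replicate 2 (adjusted p = 0.201), and Rufy4 from -5.65 to -1.29 without DRIL18 replicate 1 (adjusted p = 1) or -3.07 with limma-voom (adjusted p = 0.0727). The values of Rufy4, with 0 counts in Mock, Gpr83, with 1 count in IL12, and Timp3, with 3 counts in Mock, are fitted values that depend on the prior count of the fit. Among genes fixed in advance, Tbx21 (0.21, adjusted p = 0.00372) and Il18r1 (0.28, adjusted p = 0.000856) lay above the product. Pdcd1 (-0.87), Il12rb1 (-0.51), Il12rb2 (-0.51) and Gzmb (-0.47) lay below. Il18r1 was nevertheless below the sum, with 551 CPM in the mixture against 794, as was Il18rap, with 311 against 395. Prf1 (adjusted p = 0.852) and Il18 (adjusted p = 0.912) did not pass. Il18rap (0.18, adjusted p = 0.0449) does not pass without DRIL18 replicate 2 (0.115, adjusted p = 0.316), nor, with about the same fold change, with DESeq2 (0.19, adjusted p = 0.0564) or limma-trend (0.18, adjusted p = 0.07).

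IFN-γ response genes lay below the product although Ifng lay above it: 36 of 41 were lower and 0 higher (36 adjusted over the list alone), with a median of -0.86. Gbp2 (-2.99 ± 0.05, adjusted p = 1.04e-27) stood at 219 CPM in Mock, 732 with DRIL18, 2101 with IL12 and 884 in the mixture, and Iigp1 (-2.72) at 118, 332, 190 and 81 CPM. Gbp10 (-2.88) and Serpina3f (-2.25) also lay below the product. Interferon-stimulated genes had 24 of 43 below and 2 above (25 and 3 adjusted over the list alone), including Ifit1bl1 (-3.08) and Ifi209 (-2.72). Naive and memory genes had 17 of 30 below and 3 above (18 and 3 adjusted over the list alone), including Xcl1 (-2.32), Slamf6 (-2.17) and Klf2 (-1.46).

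Stress and NF-κB genes lay above the product. Integrated stress and amino acid genes had 24 of 30 above and 0 below (24 and 1 adjusted over the list alone; adjusted p = 0.0502 with an estimated correlation), with Slc7a11 (3.89), Chac1 (2.40) and Gpt2 (1.13). Genes of the unfolded protein response had 18 of 24 above and 0 below (19 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation), with Ern1 (1.96), Dnajb9 (0.92), Hyou1 (0.79) and Manf (0.77). NF-κB targets had 18 of 35 above and 4 below (19 and 4 adjusted over the list alone), among them Tnfrsf4 (1.95), Bcl2l1 (1.59), Cd83 (1.44) and Tnip1 (1.13).

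To ask how far the treatments changed the same genes, calls against Mock were overlapped. DRIL18 and IL12 raised 1177 genes in common, where independent lists of these sizes would share 442, and lowered 1198 in common against 452, while 481 went in opposite directions. For IL12 and the mixture the counts were 2703 against 1164, 2890 against 1186, and 567 opposite. For DRIL18 and the mixture they were 1593 against 614, 1649 against 610, and 271 opposite. Libraries simulated without any change share 0 calls in each case because almost nothing is called in them, which sets no measure for these overlaps. Across genes the fold changes of DRIL18 and IL12 correlated at r = 0.371 (0.486 in the simulation), those of DRIL18 and the mixture at 0.59 (0.497) and those of IL12 and the mixture at 0.621 (0.482), with covariances of 0.166, 0.397 and 0.644 against 0.062, 0.061 and 0.061. The r of DRIL18 and IL12 lies below that of the simulation, while the covariance lies 0.104 above. The simulated r comes from the shared Mock libraries without any treatment effect. Effects particular to a treatment lower r, so r cannot decide here whether there is an excess. All these comparisons use the same Mock libraries, so part of the overlaps may come from the shared controls, and genes are not independent of each other. The genes shared in the same direction by DRIL18 and IL12 number 1564 without Mock replicate 2, against 2375 with all libraries.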

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

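All tests of explanations in this part were chosen only after the results had been seen. The results gathered here are those where the test of the interaction passed, which means that the effect of IL12 with DRIL18 differs from its effect without DRIL18. All values are log2 of the mixture over the product of the separate effects.

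Ifng lay above the product (1.60). Among the largest values above it were Gpr83 (8.53), Gstm1 (7.89), Itgb5 (6.25), Kctd14 (6.23), Plagl1 (5.84) and Timp3 (5.42). Below it were Rufy4 (-5.65), Ret (-4.77), Timp2 (-4.64), Cdh1 (-4.32), Matn2 (-4.12) and Slc9a2 (-3.80). Rufy4 has 0 counts in Mock, and Gpr83 and Timp3 have 1 and 3 counts in a group, so their fitted values depend on the prior count of the fit. As given above, Gpr83, Plagl1, Timp3, Rufy4 and Slc9a2 shrink and lose their calls when 1 library is left out. Of the genes fixed in advance, Il18r1 (0.28), Tbx21 (0.21) and Il18rap (0.18) lay above, and Pdcd1 (-0.87), Il12rb1 (-0.51), Il12rb2 (-0.51) and Gzmb (-0.47) below. Il18r1 and Il18rap lay below the sum of the separate effects. Il18rap also shrinks to 0.115 and loses its call without DRIL18 replicate 2.

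Interferon genes lay below the product: Gbp2 (-2.99), Gbp10 (-2.88), Iigp1 (-2.72) and Serpina3f (-2.25) of the IFN-γ response, and Ifi44 (-6.05), Ifit1bl1 (-3.08), Ifi209 (-2.72) and Ifi204 (-2.43) of the interferon-stimulated genes. Ifi44 has 3 counts in Mock, with the same limit. Ifi204 is smaller and not called without DRIL18 replicate 2 (-1.69, adjusted p = 0.168). So did the naive and memory genes Xcl1 (-2.32), Slamf6 (-2.17) and Klf2 (-1.46). Among inhibitory receptor genes Nt5e (-3.22), Lag3 (-2.45) and Entpd1 (-1.61) lay below and Nr4a1 (1.67) above. Above the product lay the unfolded protein response genes Ern1 (1.96), Dnajb9 (0.92), Hyou1 (0.79) and Manf (0.77) and the NF-κB targets Tnfrsf4 (1.95), Bcl2l1 (1.59), Cd83 (1.44) and Tnip1 (1.13). The amino acid and stress genes Slc7a11 (3.89), Cth (3.33), Chac1 (2.40) and Gpt2 (1.13) lay above as well, of which Cth is not called without Mock replicate 2 (2.89, adjusted p = 0.12).

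The interaction also passed for 15 lists, here with their medians. Above the product were unfolded protein response (0.44), integrated stress and amino acids (0.41), NF-κB targets (0.37), p53 and DNA damage (0.33) and heat shock (0.13). Below were IFN-γ response (-0.86), interferon-stimulated (-0.64), inhibitory receptors (-0.61), NK cell genes (-0.59), naive and memory (-0.45), migration and adhesion (-0.41), receptors of the IL-2 family (-0.26), T cell receptor complex (-0.26), ribosomal proteins (-0.19) and cytotoxic granules (-0.037). With an estimated correlation 5 of these lists pass: IFN-γ response, interferon-stimulated, NF-κB targets, inhibitory receptors, and naive and memory. The others do not, with an adjusted p = 0.0502 for integrated stress and for NK cell genes, 0.088 for migration, 0.091 for the T cell receptor complex and 0.11 for the unfolded protein response. It is 0.15 for cytotoxic granules, 0.264 for the IL-2 family, 0.427 for p53, 0.66 for heat shock and 0.723 for ribosomal proteins.

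Ifng above the product was weighed against other causes. More delivered DRIL18 mRNA in the mixture would raise Il18 over DRIL18 alone, but its log2 fold change was -0.091 ± 0.043, which speaks against this. The value covers the reads present 24 h after electroporation, not the amount taken up or the protein. Whether the mixture received more IL-12 mRNA than IL12 alone cannot be told, since these counts do not show that mRNA. More natural killer cells would raise the NK cell list, whose median against Mock was -1.088, with 6 of 10 lower and 2 higher. The list call is lost with an estimated correlation (adjusted p = 0.115) and without the filter on low counts (adjusted p = 0.0967). Tyrobp was at -3.38 (adjusted p = 0.000484). Of the 15 genes listed, 10 stand on another list. These values therefore cannot tell a change in NK cell number from changes of these genes within T cells. IL12 alone raised both IL-18 receptor genes, the smaller change being 2.402 for Il18rap, so a stronger response to IL-18 through more receptor could contribute; receptor protein was not measured in the data used here.

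IFN-γ response genes below the product, with Ifng above it, were weighed in the same way. A wrong library scaling would move every list alike, but ribosomal proteins had a median of -0.186, closer to 0, and NF-κB targets a median of 0.368. The ribosomal list was itself called below the product by camera (adjusted p = 0.0022, and 0.723 with an estimated correlation), so it is no neutral measure. A response already at its ceiling would leave the list at or above its level with DRIL18 alone, but its median in the mixture against DRIL18 was -0.603. Fewer receptor transcripts could contribute: against DRIL18, Ifngr2 changed by -1.674 ± 0.12 (adjusted p = 1.39e-13) and Ifngr1 by -0.82 (adjusted p = 9.25e-18). Against IL12, Ifngr1 was lower in the mixture (-0.87, adjusted p = 2.86e-18) but Ifngr2 higher (1.57, adjusted p = 4.79e-09). This account covers the step from DRIL18 better than the step from IL12. Against Mock, Ifngr2 was lower with IL12 alone (-3.346) than in the mixture (-1.775). Yet IL12 alone had 17 of 41 IFN-γ response genes higher and 10 lower. Ifngr1 changed little against Mock with DRIL18 (-0.129) or IL12 (-0.08) and by -0.949 in the mixture. Ifngr1 thus followed the pattern below the product, and Ifngr2 did not.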

How the results depend on the processing

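No named gene that passed in the main fit changed its sign under any alternative. Of the named genes, 10 values changed sign that passed neither in the main fit nor in that alternative. Among these, Gzmb in IL12 against Mock was at -0.05 without IL12 replicate 1, against 0.21 without IL12 replicate 2. Of the lists, CD4 and regulatory T cell genes in IL12 against Mock had a median of 0.48 without Mock replicate 1 against -0.18, while the test kept its direction. Over 464 gene results and 8786 alternative values, 8561 stayed on the same side of the test, 215 lost the call and 10 gained it. Over 80 list results and 1280 values, 1217 stayed and 63 lost the call. The alternative with the mark bis, called library mark here, was chosen after seeing the data, and the others before.

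Gene counts moved most between Mock and NoEp. With the library mark 172 genes passed, 156 of them among the 1102, and standard errors grew, since the mark is estimated only within DRIL18 and IL12. With the replicate block 1103 genes changed. Leaving out 1 library gave 242 (without Mock replicate 1) to 1399 genes, and 2525 (without Mock replicate 2) to 4125 for DRIL18 against Mock. A group with 1 library left takes its spread from the other groups, and fewer samples give less power by construction. With only the groups compared in the fit, the counts rose to 1589 for Mock against NoEp and 4516 for DRIL18 against Mock. They fell in the comparisons with IL12, such as 7116 against 7356 for IL12 against Mock. Of the changed genes between Mock and NoEp 47.8% were higher, against 59.2% with limma-trend on the deposited values and 37.2% with the library mark; the cause was not tested. DESeq2 called fewer genes throughout, from 868 for Mock against NoEp to 8861 for the mixture against Mock; the cause was not tested.

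List calls depend on the correlation between genes. With an estimated correlation, 4 of 18 lists remained for Mock against NoEp, 5 of 27 for DRIL18, 6 of 23 for IL12 and 8 of 22 for the mixture against Mock. For the mixture 8 of 23 remained against DRIL18 and 4 of 22 against IL12, with 7 of 18 for IL12 against DRIL18 and 5 of 15 for the interaction. The rotation test fry called fewer lists for Mock against NoEp (14 against 18) and more in the other comparisons, among them IL12 against Mock (36), IL12 against DRIL18 (28) and the interaction (28). It asks whether the members move in a common direction, not whether they move more than other genes.

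Correlations of fold changes moved with the genes used. Without the filter on low counts, with 27533 genes, r was 0.444 for DRIL18 and IL12 (0.371 with it), 0.469 for DRIL18 and the mixture (0.59) and 0.513 for IL12 and the mixture (0.621). Leaving out 1 library gave 0.296 to 0.536, 0.44 to 0.639 and 0.514 to 0.669. Genes changed in the same direction by DRIL18 and IL12 numbered 1564 to 2407.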

Other observations

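The tests of the library mark and of B cells in this part were chosen only after the results had been seen, as was the choice of lists. With IL12 alone, hypoxia genes rose, 18 of 22 with 1 lower (18 and 1 adjusted over the list alone; adjusted p = 0.0923 with an estimated correlation), including Ak4 (3.11), P4ha2 (2.64), Egln3 (2.58) and Vegfa (2.42). Inhibitory receptor genes had 12 of 22 higher and 6 lower (12 and 7 adjusted over the list alone; adjusted p = 0.121 with an estimated correlation): Btla rose by 1.67, and Cd244a (-1.65) and Cd160 (-1.49) fell. In the interaction these genes lay below the product, 13 of 22 against 5 above (14 and 6 adjusted over the list alone).

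In the mixture, p53 and DNA damage genes rose against Mock, 21 of 27 with 5 lower (21 and 5 adjusted over the list alone; adjusted p = 0.155 with an estimated correlation), among them Plk2 (3.73) and Cdkn1a (2.96; 61.6 to 478 CPM). Cell cycle genes fell, 32 of 49 with 13 higher (32 and 13 adjusted over the list alone; adjusted p = 0.235 with an estimated correlation), including E2f2 (-1.13), Cenpf (-1.03) and Mki67 (-0.90). Effector transcription factors had 16 of 22 higher and 5 lower (16 and 5 adjusted over the list alone), with Zeb2 (3.23) and Hlx (3.15) higher and Eomes (-3.43) lower. Costimulatory receptors had 13 of 17 higher and 3 lower (13 and 4 adjusted over the list alone), with Tnfrsf8 (2.94) and Cd70, which rose at least 13.9-fold from 0 counts. Against IL12, NK cell genes had 6 of 10 lower and 0 higher (6 adjusted over the list alone), with Eomes (-3.40) and Gzma (-3.06; 931 to 111 CPM). NK receptor genes had 9 of 16 lower and 1 higher (9 and 1 adjusted over the list alone; adjusted p = 0.16 with an estimated correlation), with Cd7 (-3.13) and Klrb1f (-2.89), but this call (adjusted p = 0.0444) is lost without IL12 replicate 1 (adjusted p = 0.0532). Of the 15 NK cell genes listed, 10 stand on another list, so they do not mark these cells alone.

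The mark bis stands on all NoEp and no Mock libraries. Both mixture libraries carry it as well, so it separates the mixture from Mock too. With the mark as a covariate, 8486 genes changed between the mixture and Mock, against 10081 without it. If the mark stood for a difference between library preparations, the marked and unmarked libraries of DRIL18 and IL12 would differ in the same genes. The mark changed 2 genes there, and its effects correlated with those of NoEp against Mock at r = -0.029 across genes (-0.075 over the changed genes), which speaks against it as the cause of the small changes. This test rests on the unmarked replicate 1 and the marked replicate 2 of DRIL18 and of IL12. It therefore cannot tell the mark from the replicate number, nor show an effect present in only a single group. With the mark in the fit the median standard error grew from 0.093 to 0.132, all 1102 changed genes kept their sign and 156 kept the call. Fewer B cells in Mock would lower B cell genes and raise no single gene, but 47.8% of the changed genes were higher, which speaks against it as the cause of all changes. Whether it contributed to the lower genes stays open: the B cell list had a median of -0.162, with 3 of 20 past the test. Lists of gamma-delta T, CD4 and regulatory T and dendritic cells were also lower, and these cells were not weighed as a cause.

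Libraries of 1 group differed by more than counting alone. The chi-square per degree of freedom between replicates was 2.65 for Mock, 3.25 for DRIL18, 4.25 for NoEp, 4.79 for the mixture and 5.13 for IL12. Replicate numbers did not pair across groups, with correlations of the deviations from the group mean between -0.032 and 0.049. Both IL12 libraries differ along the fourth principal component, which holds 3.53% of the variance. There IL12 replicate 1, without the mark bis, lay at 26.8 and IL12 replicate 2, with it, at -26.8. The DRIL18 libraries without and with the mark lay at -0.7 and 1.8.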
